A study of Mus musculus with 12 samples.

How the data were processed

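Zic1/2 binding was profiled by CUT&RUN, in which an antibody directs a nuclease to cut DNA beside the bound protein inside nuclei. The cells were mouse cerebellar granule neurons in culture, taken on days 1, 3, 5 and 7 of culture (DIV1, DIV3, DIV5 and DIV7), with 3 libraries per day that the series design calls biological replicates. The antibody was raised to the C terminus of Zic1/2. Per the labels' protocols, cytosine arabinoside, which blocks DNA synthesis and removes dividing cells, was added at 1 uM on day 2, so the DIV1 libraries precede it. The same protocols name a commercial CUT&RUN kit and a ligation-based library kit.

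One peak list was deposited for each of the 12 libraries. The submitters' processing notes name the genome build mm10 and the tools FastQC, Trimmomatic 0.38, STAR 2.7.2b, MACS2 2.1, bedtools 2.25.0, SEACR 1.3 and DESeq2 1.36.0; the labels used here list names and versions, not the step of each. The form of the files is that of a SEACR stringent list, a caller that joins stretches of coverage into blocks. The control, the threshold and the removal of duplicate reads are not given in the sources used here. For each peak the authors gave the total signal, which is the summed coverage, and the maximum signal, which is the highest coverage, together with the part of the peak that holds the maximum; these deposited signal values are the authors' own. In 6 libraries 100% of the totals were whole multiples of 51, and in the other 6 libraries 100% were whole multiples of 50, so the total divided by this number was read as the reads in a peak. The 51-base libraries were the 3 of DIV1, DIV3 replicate 1, DIV5 replicate 3 and DIV7 replicate 3, and the 50-base libraries were all the others. Read length was therefore treated as a possible batch, and no DIV1 library lies in the 50-base group. The maximum never passed 102 in the 51-base libraries and 100 in the 50-base libraries, so it saturates at the strongest peaks. The signals were not scaled to depth. Reads in peaks ranged from 1.01 to 3.27 M per library, and the total number of reads sequenced was not used here. Depth below means reads in peaks, which depend on the peaks called as well as on the reads sequenced. A weak peak rested on few reads, with a median of 9 to 26 reads per peak over the libraries.

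Peaks on chromosomes 1 to 19, X and Y were used. The peaks of all libraries were merged where they overlapped by at least 1 bp, and a library had a region if any of its peaks overlapped it. Regions with a peak in all 12 libraries are called shared regions. At these regions the maximum signal was ranked within each library, the ranks were turned into normal scores, and limma 3.58.1 (R 4.3.3) was fitted to all 12 libraries, once with the day as a number and once with the day as a group for 5 contrasts. Values are shown as percentiles among the shared regions of a library, so a region that rose gained rank relative to the other shared regions, and no statement is made on absolute binding. The maximum signal was low, with a median over all peaks of 4 to 7 per library, so many regions tied and percentiles moved in steps. In DIV7 replicate 1, for example, some named regions tied at percentile 2.07 and others at 10.4. P-values of limma were adjusted over all shared regions by the Benjamini-Hochberg method, with a threshold of 0.05. Presence or absence of a peak was tested region by region against the day with an exact conditional trend test in regions called in 3 to 9 libraries, and between DIV1 and the later days with Fisher's exact test. Values with 1 number per library were tested by an exact two-sided permutation test of Pearson's correlation with the day, over the 369600 assignments of days to libraries. An exact test of 3 libraries against 3 cannot go below p = 0.1, so no such test was used for single values. The similarity of peak lists was the Jaccard index, the bases shared by a pair of lists divided by the bases covered by either.

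Gene positions came from a table on GRCm38.p6, the same build as mm10, with 21887 protein-coding genes. It gives the span of each gene but neither strand, exons nor transcripts. In place of the transcription start site, either end of the gene span within 1 kb was used, the nearest gene was taken by span, and exons were not separated from introns. Being nearest does not show that a gene is regulated by the region. Motifs were not tested, since no genome sequence was used here. No list of blacklisted loci was applied. The 20 gene lists, the designs and the rule for naming regions were fixed before the data were examined. The rule named the 10 rising and 10 falling shared regions with the largest coefficient, 8 regions per direction of the occupancy test, the Zic genes, the 3 members of each list with the smallest trend p, and the 5 regions of highest signal. Some results that the rule covers are not reported here. Lists were tested at shared regions with limma's camera at a preset correlation of 0.01 and with an estimated one, with limma's fry as a test against no change, and by the peaks of each library inside the gene spans extended by 5 kb, per 10000 peaks of that library. Lists were also set against 10000 random lists of genes matched in length over 20 bins. Alternatives covered the signal measure, its scaling, the set of regions, the overlap and the peak threshold. They also covered the replicate number as a block, array weights, and leaving out each library. Depth, read length and the 3 libraries with fewest reads were added after the data were seen. Leaving out those 3 keeps DIV7 replicate 2 as the only DIV7 library. That setting therefore cannot tell depth from the loss of the last day.

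The limma trend and the occupancy trend were tried on simulated changes. For the trend at the 12276 shared regions, limma recovered 0%, 52.5% and 70.5% of 200 regions changed by 2, 4 and 8-fold between DIV1 and DIV7, with 0, 5 and 8 false calls. The exact occupancy trend recovered 90% of 200 changed regions at an unadjusted p under 0.05 and 0 after adjustment. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.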

Results

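Zic1 and Zic2 are zinc finger transcription factors of cerebellar granule neurons and their progenitors. Their binding was followed by CUT&RUN in 12 libraries of cultured mouse granule neurons, 3 at each of DIV1, DIV3, DIV5 and DIV7, to ask how it changes as the neurons mature. The lists held 65102 to 89417 peaks per library. Merging them gave 286729 regions, of which 180541 were called in a single library and 12276 in all 12. The shared regions covered 23.9 Mb with a median width of 1689.5 bp, and 58.4% of them lay within 1 kb of a gene end, against 5.05% of regions called in 1 library. They reached 10086 of 21887 protein-coding genes (46.1%) within 5 kb of the gene span.

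The number of Zic1/2 peaks did not follow the day, but the lists of later days held fewer reads and narrower peaks. The mean number was 72650 ± 9988.8 (SD, n = 3) at DIV1 and 71963.7 ± 6294.74 at DIV7 (r = 0.0650, exact p = 0.840; rho = 0.0648, exact p = 0.864). Reads in peaks were 2.96 ± 0.285 M at DIV1, 2.5 ± 0.516 at DIV3, 2.14 ± 0.549 at DIV5 and 1.68 ± 0.748 at DIV7 (r = -0.722, exact p = 0.00889; rho = -0.713, exact p = 0.0134). The covered length fell from 40.4 ± 2.71 to 26.9 ± 8.79 Mb (r = -0.704, exact p = 0.01; rho = -0.713, exact p = 0.0134) and the median width from 391 ± 49.7 to 268 ± 43.6 bp (r = -0.756, exact p = 0.00409; rho = -0.799, exact p = 0.00341). Regions seen in 1 library only made up 16.3 ± 5.73% of a list at DIV1 and 31.9 ± 7.50% at DIV7 (r = 0.752, exact p = 0.00580; rho = 0.734, exact p = 0.01). These were among 13 measures, and each of the 4 relations had a Benjamini-Hochberg value of 0.0183, against 0.931 for the number of peaks. Over all choices of 2 DIV1 or DIV7 libraries left out, r stayed between -0.835 and -0.539 for reads, -0.825 and -0.511 for covered length, -0.831 and -0.625 for width, and 0.590 and 0.890 for single-library regions; for the number of peaks it ranged from -0.278 to 0.503. Within the 50-base libraries r was -0.344 for reads (exact p = 0.533) and -0.399 for covered length (exact p = 0.444), and within the 51-base libraries it was -0.882 (exact p = 0.0417) and -0.914 (exact p = 0.0250). For width these were -0.542 (exact p = 0.311) and -0.745 (exact p = 0.108), and for single-library regions 0.597 (exact p = 0.222) and 0.808 (exact p = 0.0750).

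**Figure D1:**
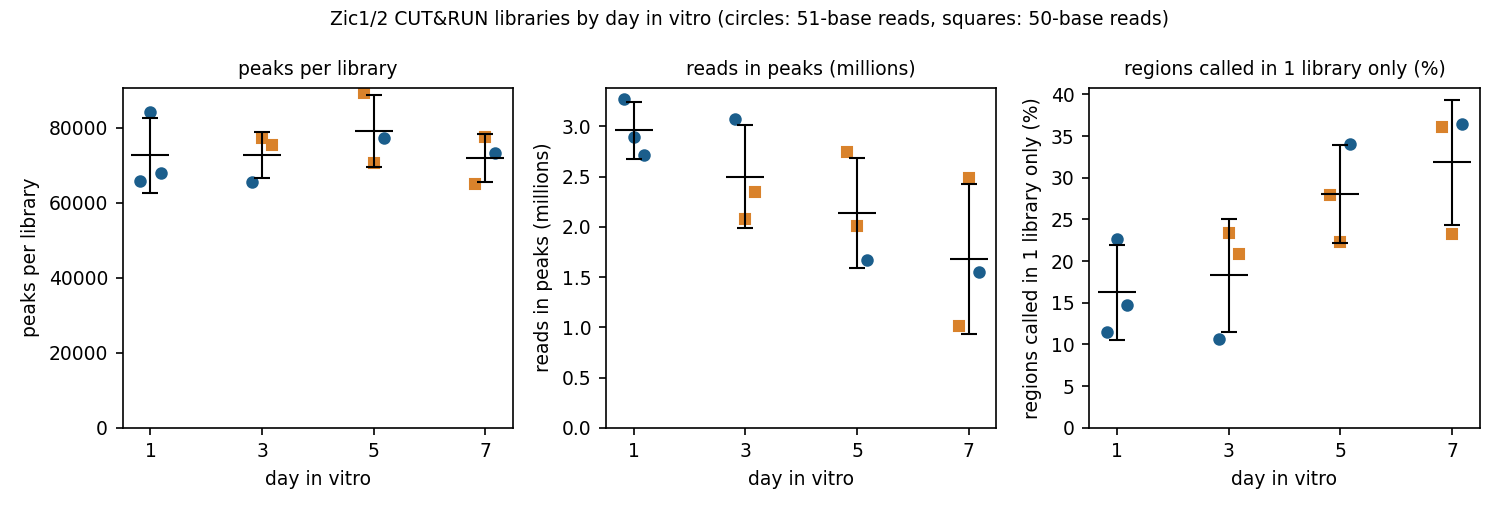
Peaks per library, reads in peaks (M), and the percentage of a library's regions called in no other library, by day in vitro; circles are 51-base and squares 50-base libraries, and black bars give the mean and SD of 3 libraries. Reads in peaks run from 3.27 M in DIV1 replicate 1 to 1.01 M in DIV7 replicate 1, while the number of peaks shows no trend.

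Zic1/2 peaks inside genes became a smaller part of the lists with the day, and peaks between genes a larger part. Peaks inside gene spans made up 44.5 ± 0.371% of a list at DIV1 (n = 3), 41.6 ± 2.60% at DIV3, 38.9 ± 1.39% at DIV5 and 38.2 ± 3.73% at DIV7 (r = -0.765, exact p = 0.00542, adjusted over 3 classes 0.0163; rho = -0.777, exact p = 0.00507). Peaks between genes made up 35.5 ± 1.77% at DIV1 and 41.8 ± 3.09% at DIV7 (r = 0.715, exact p = 0.0121, adjusted 0.0181; rho = 0.734, exact p = 0.01). The share within 1 kb of a gene end was 20 ± 1.41% at DIV1 and 20 ± 0.959% at DIV7 (r = -0.0247, exact p = 0.939; rho = 0.0216, exact p = 0.973). Leaving out 2 DIV1 or DIV7 libraries gave r between -0.908 and -0.620 for peaks in genes, 0.520 and 0.855 for peaks between genes, and -0.379 and 0.407 near gene ends. In the 51-base libraries r was -0.934 in genes (exact p = 0.0167), 0.891 between genes (exact p = 0.0333) and -0.335 near gene ends (exact p = 0.483), but in the 50-base libraries it was -0.244 (exact p = 0.644), -0.0712 (exact p = 0.889) and 0.490 (exact p = 0.333), so the relation did not hold within both. Without DIV1 replicate 1 the adjusted exact p between genes was 0.0516, and without the 3 libraries with fewest reads (DIV5 replicate 3, DIV7 replicate 1 and DIV7 replicate 3) it was 0.182 for both classes.

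Peak lists of the same day resembled each other more, on average, than lists of different days. This rested on DIV1 and did not hold at DIV5 or DIV7. DIV3 lists were about as close to DIV1 lists as to each other. The mean Jaccard index was 0.341 for pairs of the same day and 0.300 for pairs of different days, a difference of 0.0409 (exact p = 0.000844 over 15400 partitions). It was 0.441 ± 0.0238 (SD over 3 pairs) among DIV1 libraries, 0.378 ± 0.0272 among DIV3, 0.309 ± 0.0380 among DIV5 and 0.237 ± 0.0312 among DIV7 libraries. DIV1 libraries had a mean index of 0.376 with DIV3, 0.311 with DIV5 and 0.256 with DIV7. DIV3 libraries had 0.329 with DIV5 and 0.263 with DIV7, and DIV5 libraries 0.267 with DIV7. On average, DIV7 libraries thus resembled each other less than those of any other day. The deepest DIV3 library, replicate 1 with 3.08 M reads in peaks, had 0.459, 0.408 and 0.432 with DIV1 replicates 1, 2 and 3. DIV1 libraries had 0.440, 0.465 and 0.418 with each other, so depth cannot be told apart from the day. The difference rested on DIV1, since it was 0.0225 (exact p = 0.0628) without DIV1 replicate 1, 0.0243 (exact p = 0.0705) without DIV1 replicate 2 and 0.0242 (exact p = 0.0645) without DIV1 replicate 3. Within the 50-base libraries it was 0.00625 (exact p = 0.267), where 15 partitions cannot give a p under 0.05, and the 51-base libraries hold a single library at each later day.

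**Figure D2:**
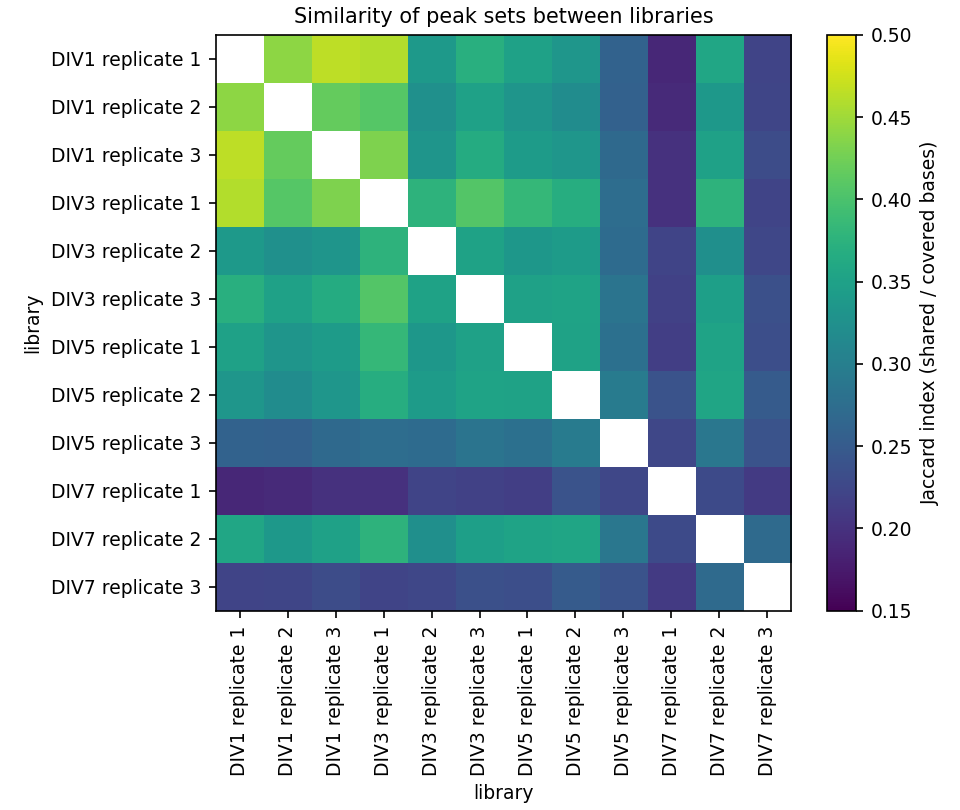
Jaccard index (bases shared by a pair of peak lists over bases covered by either) for each pair of the 12 libraries, ordered by day and replicate. The index runs from 0.190 between DIV1 replicate 1 and DIV7 replicate 1 to 0.465 between DIV1 replicates 1 and 3.

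No single region passed the test for gain or loss of a Zic1/2 peak over the days. Of 52519 regions tested by the exact trend test with Benjamini-Hochberg adjustment, 0 passed (lowest adjusted exact p = 0.134), while 6798 had an unadjusted p under 0.05, 982 of them with more peaks late and 5816 with more peaks early, against 958 expected. Without the 3 libraries with fewest reads the split was 1739 late and 3624 early, and with the maximum-signal parts of peaks 3287 regions had such a p, 565 late and 2722 early. The late count was 2056, 2200 and 2072 without DIV5 replicates 1, 2 and 3 and 1556 without DIV7 replicate 1, and 264 where peaks had to cover at least 50% of the region, against 5965 early. A peak in all DIV1 and DIV3 libraries and in no DIV5 or DIV7 library was found in 356 regions, 22 of them within 1 kb of a gene end. The reverse was found in 26 regions, 0 of them near a gene end. These 382 regions carried the smallest p the test can give, an exact p = 0.00216, and 2274 would be needed for any to pass. The 8 early regions with the highest signal lay nearest to Chrnb4, a nicotinic acetylcholine receptor subunit (chr9: 55055334 to 55056470, mean percentile 94.4), Pipox, Tafa5, Grip1, which codes for a scaffold of glutamate receptors, Ano5, Adra2a, Casp12 and Rtl1. The 8 late regions lay nearest to Fgf12, a modulator of sodium channels (chr16: 28475253 to 28476315, mean percentile 72.7), A530032D15Rik, Map4k3, Serp2, C6, Btbd35f25, Paqr8 and Cela3a. None of these 16 passed.

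DIV1, the day before cytosine arabinoside, was also set against the later days. With Fisher's exact test and Benjamini-Hochberg adjustment 0 of 274453 regions passed, and 8091 had an unadjusted p under 0.05. The smallest p it can give, a Fisher's exact p = 0.00455, was reached by 968 regions in both directions together. These were too few for any to pass over so many tests, so the 0 cannot show that no region differed. Of the 8091, 7123 were called more often at DIV1 and 968 more often at DIV3, DIV5 and DIV7. Leaving out any library lowered the number of 8091 by over 1.5 times, but the steps of the test also change with fewer libraries. The smallest Fisher's exact p rises to 0.0182 without a DIV1 library and to 0.00606 without a later one, so fewer patterns can pass 0.05. The drop therefore does not show the weight of any library. The number was 1933, 2024 and 2217 without DIV1 replicates 1, 2 and 3, and 3829, 3159 and 3230 without those of DIV3. It was 3056, 2922 and 2904 without those of DIV5, and 2915, 3087 and 3020 without those of DIV7.

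At the shared regions, the relative Zic1/2 signal changed with the day at a small part of sites, with more falling than rising. By limma with Benjamini-Hochberg adjustment, 251 of 12276 regions passed, 91 rising and 160 falling. Total signal gave 923 regions, 339 rising and 584 falling, regions called in at least 10 of 12 libraries gave 532, 400 of them falling, and regions of at most 2 kb gave 77. Sites far from gene ends were over-represented, since 25 of the 91 rising (27.5%) and 25 of the 160 falling regions (15.6%) lay within 1 kb of a gene end, against 58.6% and 59.0% of the respective other shared regions (Fisher's exact p = 2.65e-09 and 3.45e-29; regions are not independent replicates). Several falling regions clustered at 1 gene, with 3 each nearest to Ephb2, a receptor of axon guidance, Gse1 and Llgl1, a regulator of cell polarity, and 4 rising regions were nearest to Sfi1. Of the rising regions 28.6% had a predicted gene nearest, against 6.7% of the others. Blacklisted loci were not removed, so a rise at Sfi1 or at predicted genes cannot be taken as a gain of Zic1/2 binding. The split between rising and falling depended on scaling, as log2 signal centred on the library median gave 430 regions, 244 rising and 186 falling. With log2 reads in peaks as a covariate 9 passed, with all 251 coefficients keeping their sign; without the 3 libraries with fewest reads 101 passed, and with the read length as a term 190. Within the 50-base libraries 0 passed and within the 51-base libraries 0 passed, with 1141 and 1829 at an unadjusted p under 0.05. The count was 113 without DIV1 replicate 1, 80 without DIV1 replicate 2, between these without DIV1 replicate 3, 163 without DIV3 replicate 1, 138 without DIV7 replicate 1 and 142 without DIV7 replicate 3.

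Of the 10 regions that fell most, 9 had a mean percentile of 67.3 or more at DIV1 and 8 one of 11.9 or less at DIV7, and 9 of the 10 lay within the span of their gene. A region in Fam53b (chr7: 132758268 to 132760943) fell from percentile 94.2 ± 4.49 (SD, n = 3) at DIV1 to 11.9 ± 12.9 at DIV7, with a coefficient of -0.541 ± 0.0714 (SE) normal score units per day (limma adjusted p = 0.00505), and 229 to 290 reads per library at DIV1 against 7 to 30 at DIV7. It also passed with depth as a covariate (limma adjusted p = 0.00558). In Bcl7a, a subunit of the BAF chromatin remodelling complex (chr5: 123345966 to 123347204), the percentile fell from 88.4 ± 6.24 to 5.17 ± 4.90 (limma adjusted p = 0.00505). In Nol4l (chr2: 153479453 to 153482597) it fell from 67.3 ± 26.3 to 2.30 ± 2.13, and beside a gene end of Vash2, a tubulin carboxypeptidase (chr1: 190947883 to 190949670), from 70.5 ± 19.4 to 2.39 ± 1.90. In Pde2a, a cyclic nucleotide phosphodiesterase (chr7: 101454372 to 101457042), it fell from 97.5 ± 0.186 to 32.9 ± 19.5 (limma adjusted p = 0.00776). A region 16692 bp from Gm829 (chr4: 45740398 to 45742813) fell from 73.8 ± 11.1 to 4.39 ± 5.26. These 6 passed without any single library. The other 4 lay in Zfp469 (38.9 ± 10.1 to 1.5 ± 2.54), Mrps27 (74.0 ± 18 to 4.18 ± 5.41), Man1c1 (79.3 ± 14.0 to 5.46 ± 4.55) and Rasgef1a (93.2 ± 1.93 to 25.1 ± 19.8). Each lost its call without 1 library. The limma adjusted p of Man1c1 was 0.0609, 0.0691 and 0.0791 without DIV1 replicates 1, 2 and 3. That of Zfp469 was 0.0556, 0.0551 and 0.0666 without those libraries, 0.0912 without DIV7 replicate 1 and 0.0816 without DIV7 replicate 3, and that of Rasgef1a was 0.0722, 0.0757, 0.0610, 0.0539 and 0.0808 in the same order. For Mrps27 it was 0.0930 and 0.0605 without DIV1 replicates 2 and 3, 0.0542 without DIV5 replicate 2, and 0.0701, 0.0773 and 0.104 without DIV7 replicates 1, 2 and 3. With depth as a covariate Fam53b alone of the 10 passed, though the coefficients kept their sign and most their size, such as -0.489 against -0.465 for Bcl7a, -0.447 against -0.458 for Nol4l and -0.591 against -0.426 for Man1c1, but -0.252 against -0.422 for Rasgef1a and -0.291 against -0.428 for Zfp469. With read length as a term Man1c1 lost its call (limma adjusted p = 0.0713).

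Of the 10 regions that rose most, 8 had a mean percentile of 12.9 or less at DIV1, the others being those nearest to Nbea and Fbxw4. In Foxn3, a forkhead transcription factor (chr12: 99215078 to 99217879), the percentile rose from 7.10 ± 7.99 at DIV1 (n = 3) to 87.2 ± 8.68 at DIV7, with a coefficient of 0.518 ± 0.0768 per day (limma adjusted p = 0.00505), and 24 to 44 reads against 68 to 269. A region 42733 bp from Map4k4, a kinase of the JNK pathway (chr1: 39856810 to 39858169), rose from 9.51 ± 0.616 to 90.4 ± 5.67 (limma adjusted p = 0.00505), and it alone of the 10 passed with depth as a covariate (limma adjusted p = 0.0328). Regions near the predicted genes Gm21149 (chr5: 15489638 to 15491320) and Gm10354 (chr5: 14956933 to 14957893) rose from 11 ± 17.9 to 86.4 ± 10.3 and from 1.81 ± 2.04 to 72.7 ± 26.3. These 4 passed without any single library. The other 6 lay in or nearest to Sfi1 (10.9 ± 13.4 to 82.7 ± 22.8), Nbea (25 ± 29.2 to 94.0 ± 6.39), Fbxw4 (31.2 ± 24.4 to 97.7 ± 1.24), Oxsm (3.53 ± 2.05 to 85.8 ± 6.77), Gsto1 (12.9 ± 10.5 to 90.7 ± 6.25) and Gm21083 (5.94 ± 3.17 to 76.6 ± 28.2). Sfi1 lost its call without DIV1 replicate 2 (limma adjusted p = 0.0564), and Nbea without DIV1 replicates 1 and 3 (0.0569 and 0.0549). The limma adjusted p of Gm21083 was 0.0582 and 0.0578 without DIV1 replicates 2 and 3 and 0.0505 without DIV7 replicate 3. For Fbxw4 it was 0.104, 0.0556, 0.0828 and 0.0603, and for Gsto1 0.0609, 0.0771, 0.0896 and 0.0599, without DIV1 replicates 1, 2 and 3 and DIV7 replicate 3. For Oxsm it was 0.122, 0.118 and 0.120 without DIV1 replicates 1, 2 and 3, 0.0526 without DIV3 replicate 1, 0.0519 and 0.0580 without DIV5 replicates 1 and 2, and 0.0522 and 0.0707 without DIV7 replicates 1 and 3. The Oxsm region was already at percentiles 62.5, 92.6 and 84.7 in DIV3 replicates 1, 2 and 3, so most of its rise lay between DIV1 and DIV3. With depth as a covariate the coefficient was 0.559 against 0.518 for Foxn3, 0.540 against 0.473 for Nbea and 0.542 against 0.439 for Oxsm, but 0.246 against 0.486 for Sfi1, 0.234 against 0.425 for Gm21083 and 0.318 against 0.524 for Gm10354. With read length as a term Fbxw4, Gsto1 and Oxsm lost their calls (limma adjusted p = 0.0891, 0.0792 and 0.127).

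**Figure D3:**
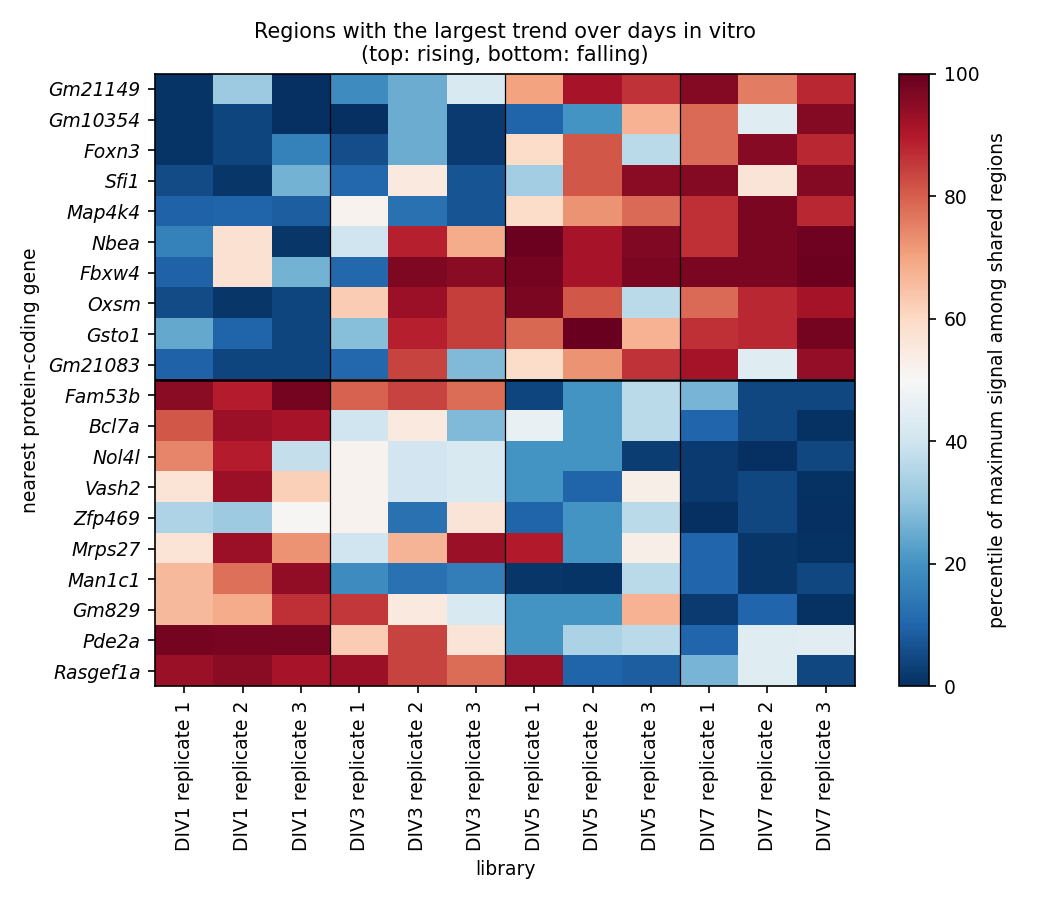
Percentile of maximum signal among the 12276 shared regions of each library, for the 10 rising (top) and 10 falling (bottom) regions with the largest trend coefficient, labelled by the nearest protein-coding gene. Fam53b goes from a mean of 94.2 at DIV1 to 11.9 at DIV7, and Map4k4 from 9.51 to 90.4.

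In DIV7 against DIV1, limma called 232 regions, 90 higher and 142 lower. It called 876 with total signal, 407 among regions called in at least 10 of 12 libraries and 79 among regions of at most 2 kb. The named regions had been chosen by their trend over the same libraries, so their direction here was largely set by that choice. Fam53b differed by -2.99 ± 0.421 normal score units (limma adjusted p = 0.0105), Bcl7a by -3.04 ± 0.385 (0.00437), Foxn3 by 2.90 ± 0.462 (0.0105) and Map4k4 by 2.69 ± 0.404 (0.0105), whereas Rasgef1a, at -2.32 ± 0.608, did not pass (0.0630). The log2 signal centred on the library median gave 177 higher and 144 lower. With the read length as a term 6 regions passed, and with depth as a covariate 18. Without the 3 libraries with fewest reads, DIV7 replicate 2 is the only DIV7 library, so no count is given for that setting. The count was 78, 75 and 24 without DIV1 replicates 1, 2 and 3, and 115 and 118 without DIV7 replicates 1 and 3.

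DIV3 followed the addition of cytosine arabinoside, and in DIV3 against DIV1 limma called 40 regions, 35 higher and 5 lower (120 with total signal, 91 higher and 29 lower). Of the strongest, chosen after their values were seen, a region in Ntn1, which codes for the guidance cue netrin-1 (chr11: 68232753 to 68234464), fell from percentile 91.2 ± 2.06 (n = 3) to 15.3 ± 11.4 (limma adjusted p = 0.0455). A region 55540 bp from Hes1, a Notch and hedgehog target of progenitors, fell from 71.0 ± 22.6 to 10.4 ± 5.12 (limma adjusted p = 0.0497). These lower regions lost their calls without any single DIV1 or DIV3 library and without DIV5 replicate 1 or 2, where limma called 0 lower regions. With the replicate number as a block limma called 0 lower regions too. The other 3 lower regions were nearest to Fam222b, Amotl2 and Gm3739. Not all stayed low. At DIV7 the mean percentiles of Fam222b and Amotl2 were 74.0 and 76.3, against 6.25 and 36.0 at DIV3, and that of Hes1 was 43.4. Those of Ntn1 and Gm3739 were 23.8 and 51.1 at DIV7. A region 145626 bp from Astn2, a gene of granule neuron migration, rose from 4.08 ± 4.78 to 94.4 ± 1.21 (limma adjusted p = 0.0108), followed by regions nearest to Pdha2, Dhrs2, Oprm1 and Ggact. Oprm1 and Ggact went from mean percentiles of 82.6 and 87.8 at DIV3 to 18.7 and 24.1 at DIV7. Astn2, Pdha2 and Dhrs2 were at 78.6, 83.2 and 74.4 at DIV7. With the read length as a term 3 regions passed. The count was 6, 2 and 1 without DIV1 replicates 1, 2 and 3, 1, 8 and 2 without DIV3 replicates 1, 2 and 3, and 16 and 22 without DIV5 replicates 1 and 2, which add only to the estimate of the spread. The log2 signal centred on the library median gave 10 higher and 0 lower.

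Between neighbouring later days no region passed. In DIV5 against DIV3 and in DIV7 against DIV5, limma called 0 regions, with 1000 and 1129 at an unadjusted p under 0.05. Ranks of total signal gave 3 and 38 regions. In DIV7 against DIV3 limma called 140 regions, 42 higher and 98 lower (652 with total signal), and the log2 signal centred on the library median gave 51 higher and 62 lower. The count was 77 without DIV1 replicate 1, 85 without DIV1 replicate 3, 0, 0 and 15 without DIV3 replicates 1, 2 and 3, 38 without DIV7 replicate 1 and 0 without DIV7 replicate 3, and it was 4 with depth as a covariate.

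Most Zic genes themselves carried Zic1/2 peaks at every day. Of 5 Zic genes 4, all but Zic4, had a shared region within 5 kb. Random lists of genes of the same length had a median of 2 (adjusted permutation p = 0.326). The shared regions nearest to a Zic gene numbered 7, and 0 passed the trend test by limma, either over all regions or adjusted over the list alone. The strongest lay at a gene end of Zic5 (chr14: 122464394 to 122466615), at percentile 87.4 ± 1.53 at DIV1 (n = 3) and 57.7 ± 10.2 at DIV7 (limma adjusted p = 0.218). At Zic2 (chr14: 122472236 to 122476438) the percentile was 73.1 ± 24.3 and 78.3 ± 2.77, and 2155 bp from Zic1 (chr9: 91353517 to 91355903) 6.07 ± 2.47 and 14.4 ± 12.4. The highest signal of all was reached at loci of another kind, such as chr9: 2999995 to 3038425 and chr2: 98662152 to 98663096. There the maximum signal lay at its ceiling in all 12 libraries, at a mean percentile of 99.97, and such loci were not filtered here.

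Peaks at progenitor, granule neuron and axon genes made up less of the lists with time in culture, as did peaks at interneuron, oligodendrocyte, forebrain and Hox genes. Of 20 fixed lists, 9 passed the exact permutation test of peaks per 10000 with Benjamini-Hochberg adjustment, 8 falling and 1 rising. Sonic hedgehog and progenitor genes fell from 24.2 ± 1.19 (n = 3) at DIV1 to 15.5 ± 2.89 at DIV7 (r = -0.799, exact p = 0.00265, adjusted 0.00756), genes of granule neuron identity from 28.7 ± 1.97 to 17.7 ± 6.28 (r = -0.802, exact p = 0.00183, adjusted 0.00610), axon growth and migration genes from 41.6 ± 1.05 to 28.8 ± 7.28 (r = -0.741, exact p = 0.00510, adjusted 0.0113), and NFI and MEF2 factors from 26.1 ± 2.07 to 15.6 ± 4.26 (r = -0.833, exact p = 0.000936, adjusted 0.00468). Markers of inhibitory interneurons fell from 7.20 ± 1.09 to 2.33 ± 0.346 (r = -0.880, adjusted exact p = 0.000703), of the oligodendrocyte lineage from 7.46 ± 0.432 to 2.58 ± 1.08 (r = -0.882, adjusted exact p = 0.000758), forebrain transcription factors from 5.52 ± 0.663 to 1.42 ± 0.334 (r = -0.883, adjusted exact p = 0.000649) and Hox genes from 1.51 ± 0.0366 to 0.333 ± 0.178 (r = -0.793, adjusted exact p = 0.0107). Markers of Purkinje cells rose from 6.03 ± 0.429 to 9.44 ± 0.944 (r = 0.825, exact p = 0.00130, adjusted 0.00519). Mature synapse genes were at 33.5 ± 2.19, 41.2 ± 4.49, 36.5 ± 5.77 and 30.9 ± 8.70 at DIV1, DIV3, DIV5 and DIV7 (adjusted exact p = 0.505). A rise followed by a fall is not what this trend test looks for. Housekeeping genes were at 4.91 ± 0.533 at DIV1 and 4.78 ± 0.348 at DIV7 (0.628). Within the 50-base and within the 51-base libraries 0 lists passed, with r of the same sign as the pooled one in all 9, which were chosen over the same libraries. Without the 3 libraries with fewest reads 4 passed, the interneuron, oligodendrocyte and forebrain lists falling and the Purkinje list rising.

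**Figure D4:**
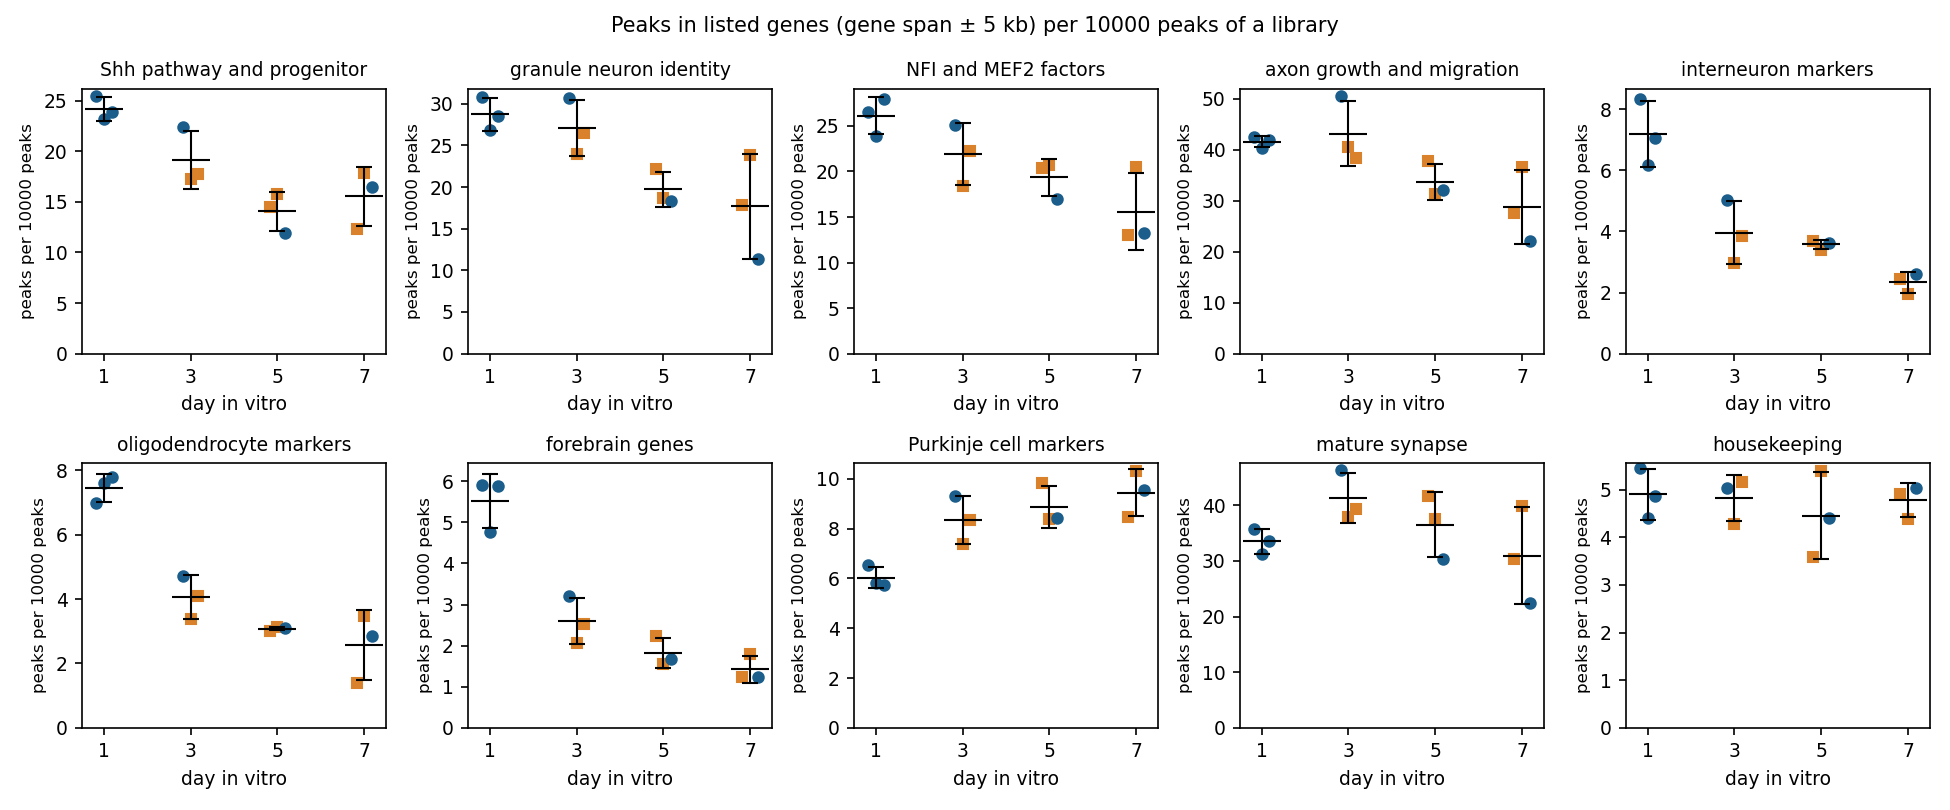
Peaks within 5 kb of the genes of 10 fixed lists, per 10000 peaks of the library, by day in vitro; circles are 51-base and squares 50-base libraries, and bars give the mean and SD of 3 libraries. Interneuron markers go from 7.20 at DIV1 to 2.33 at DIV7 and Purkinje cell markers from 6.03 to 9.44.

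The genes behind these lists, with examples chosen after their values were seen, were tested one by one with the same exact permutation test. In the progenitor list 4 of 18 genes fell, adjusted over the list alone, and 4 adjusted over all listed genes. Gli2, a transcription factor of the hedgehog pathway, fell from 5.16 ± 0.288 to 1.99 ± 0.796 peaks per 10000 (n = 3), on 34 to 41 peaks per library at DIV1 and 7 to 19 at DIV7 (exact p = 0.000249, 0.00224 over the list alone). Ccnd2, a D-type cyclin, fell from 1.89 ± 0.0969 to 0.360 ± 0.186 (exact p = 1.6e-05), and Atoh1, the proneural factor of granule progenitors, from 0.685 ± 0.0691 to 0.226 ± 0.140 (exact p = 0.00473). In the granule neuron list 5 of 14 genes fell, adjusted over the list alone, and 4 over all listed genes. Rbfox3, which codes for NeuN, fell from 13.4 ± 1.29 to 7.72 ± 3.63 (exact p = 0.00175), and Nhlh1, a factor of newly postmitotic neurons, from 0.836 ± 0.107 to 0 in each DIV7 library (exact p = 0.000103). In the axon list 10 of 26 genes fell and 1 rose, adjusted over the list alone, and 5 and 1 over all listed genes. Ntn1 fell from 3.41 ± 0.504 to 0.943 ± 0.555 (exact p = 5.4e-05) and the rising gene was Nrp1, a semaphorin receptor, from 0.367 ± 0.0698 to 0.821 ± 0.385 (exact p = 0.00627). Nfia fell from 8.44 ± 0.494 to 3.6 ± 1.4 (exact p = 0.000287). Of 8 NFI and MEF2 genes 3 fell, adjusted over the list alone, and 2 over all listed genes.

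Among markers of other cells and tissues, few peaks stood behind each gene. In the interneuron list 6 of 12 genes fell, adjusted over the list alone, and 4 over all listed genes, and in the forebrain list 7 and 4 of 12. In the oligodendrocyte list 3 of 12 fell by either adjustment, Pdgfra from 1.76 ± 0.392 to 0.598 ± 0.192 peaks per 10000 (n = 3, exact p = 0.000168), Olig2 from 0.695 ± 0.164 to 0 in each DIV7 library (exact p = 0.000254) and Mbp from 2.20 ± 0.0681 to 0.771 ± 0.289 (exact p = 0.000952). Lhx5, of the interneuron list, fell from 0.747 ± 0.158 to 0.0909 ± 0.157 (exact p = 0.00110). No Hox gene passed alone by the exact permutation test (0 of 16), and the whole Hox list held 1 to 13 peaks per library. Of 12 Purkinje genes 3 rose, adjusted over the list alone, and 1 over all listed genes. They included Rora, a nuclear receptor (2.2 ± 0.18 to 3.81 ± 0.655, exact p = 0.00376), and Foxp2 (0.317 ± 0.149 to 0.738 ± 0.188, exact p = 0.00802).

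At shared regions 0 of 18 lists passed camera, which sets a list against all other regions, the lowest adjusted p being 0.120 for granule neuron identity (lower with the day; adjusted p = 0.506 with an estimated correlation), with 2 lists at an unadjusted p under 0.05 besides it, axon growth and Wnt. With the read length as a term the granule neuron list had an adjusted p of 0.0356. Against no change at all, limma's fry gave an unadjusted p of 0.0106 for Wnt and 0.0116 for granule neuron genes. For changes in either direction many lists had a low unadjusted p, from 3.75e-07 for axon genes to 0.000142 for Wnt, 0.000222 for activity-regulated, 0.000771 for cell cycle and 0.00428 for progenitor genes. Single members had called regions. In Rbfox3 a region (chr11: 118738465 to 118741048) fell from percentile 71.8 ± 3.06 (n = 3) to 6.83 ± 6.31 (limma adjusted p = 0.00776) and in Nfia (chr4: 97648757 to 97650550) from 62.5 ± 5.89 to 8.45 ± 3.39 (0.0170), and both passed without any single library. Regions at or near Cbln3, a synaptic organizer of mature granule neurons (27.4 ± 9.67 to 80.4 ± 11.6), and Rora (23.6 ± 18.9 to 91.3 ± 4.47) rose, and those at or near Arc (67.5 ± 14.8 to 13.9 ± 11.5), Mbp (50.0 ± 20.7 to 6.46 ± 3.42) and Mki67, 365195 bp away (84.6 ± 9.23 to 30.4 ± 12.6), fell. The limma adjusted p of Rora was 0.0925, 0.0564 and 0.0915 without DIV1 replicates 1, 2 and 3. That of Cbln3 was 0.0609 and 0.0704 without DIV1 replicates 1 and 2 and 0.0881 and 0.0837 without DIV7 replicates 1 and 3, and that of Mki67 was 0.0771 and 0.0605 without DIV1 replicates 2 and 3 and 0.0602 and 0.0520 without DIV7 replicates 1 and 2. Arc lost its call without any of 10 libraries, all but DIV3 replicates 1 and 2 (0.0523 to 0.120), and Mbp without any of 10 libraries, all but DIV3 replicate 3 and DIV5 replicate 3 (0.0553 to 0.137). With depth as a covariate none of these 7 passed (limma, lowest adjusted p = 0.146), with coefficients of -0.342 against -0.364 for Rbfox3, -0.273 against -0.290 for Nfia, 0.382 against 0.345 for Rora and -0.395 against -0.331 for Mki67. With read length as a term the limma adjusted p was 0.0787 for Rora, 0.0960 for Arc, 0.140 for Mbp and 0.0713 for Mki67. Adjusted over the list alone, 1 region rose and 1 fell among activity-regulated, synapse and Wnt genes each, 2 fell at oligodendrocyte genes, 1 fell at progenitor, cell cycle, granule neuron, NFI and MEF2 and interneuron genes each, and 1 rose at Purkinje genes.

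Shared Zic1/2 regions reached some gene groups more often than others at all days. Every one of 17 chromatin regulators had a shared region within 5 kb, against a median of 10 in random lists of genes of the same length (adjusted permutation p = 0.0040), as did 13 of 15 activity-regulated genes, all but Bdnf and Nptx2, against 7 (0.0173). Of 12 microglia markers 1 did, against 6 (0.0330), and of 16 Hox genes 0, against 6 (0.0040). Hox genes lie side by side in clusters, which the random lists did not match. The p for Hox genes thus treats neighbours as independent. The other 16 lists did not pass. Mature synapse genes had 24 of 30 (0.0600), housekeeping genes 10 of 12 against 5 (0.0567) and forebrain genes 1 of 12 (0.0567).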

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

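Alternatives of depth, read length and the 3 libraries with fewest reads in peaks were chosen after seeing the data; all others were chosen before the data were examined. Of the values that answer a comparison, 195 stayed the same, 53 were weaker and 15 stronger; of the others 1843 stayed the same, 106 were weaker, 38 stronger, 15 moved and 1 reversed, the share of peaks between genes within the 50-base libraries (r = -0.0712, exact p = 0.889). The counts for the trend, DIV7 against DIV1, DIV3 against DIV1, DIV5 against DIV3, DIV7 against DIV5 and DIV7 against DIV3 at shared regions were 251, 232, 40, 0, 0 and 140 by limma, and 923, 876, 120, 3, 38 and 652 with total signal. Quantile-normalized log2 signal gave 1 region in DIV7 against DIV5, and median-centred log2 signal gave 430 for the trend and 10 in DIV3 against DIV1. Regions called in at least 10 of 12 libraries gave 532 for the trend, 407 in DIV7 against DIV1 and 217 in DIV7 against DIV3; regions of at most 2 kb gave 77, 79 and 68. Array weights gave 67 in DIV3 against DIV1 and 91 in DIV7 against DIV3. Depth as a covariate gave 9 for the trend, 18 in DIV7 against DIV1 and 4 in DIV7 against DIV3, and read length as a term gave 190 for the trend, 145 in DIV7 against DIV3, 6 in DIV7 against DIV1, 3 in DIV3 against DIV1 and 1 gene list at shared regions against 0. Without the 3 libraries with fewest reads, the trend had 101 regions, DIV7 against DIV1 33, DIV3 against DIV1 63 and DIV7 against DIV3 0, and 4 gene lists by peaks per library and 0 genomic classes passed. Within the 50-base and within the 51-base libraries 0 regions of the trend, 0 gene lists and 0 genomic classes passed, where fewer libraries were tested; the difference in similarity within the 50-base libraries was 0.00625 (exact p = 0.267). Covered bases in place of the number of peaks gave r = -0.704 (exact p = 0.01). The cause was not tested for the other changes.

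Leaving out each library in turn gave 80 to 299 regions for the trend, 24 to 232 in DIV7 against DIV1, 1 to 57 in DIV3 against DIV1, 0 to 185 in DIV7 against DIV3, and 0 to 0 in DIV5 against DIV3 and DIV7 against DIV5. It gave 9 to 13 gene lists by peaks per library, 0 to 0 at shared regions, 1 to 2 genomic classes, 0 to 0 regions in both occupancy tests, a difference in similarity of 0.0225 to 0.0677, and r of -0.0832 to 0.279 for the number of peaks.

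The replicate number as a block gave 186, 238, 11, 0, 0 and 104 regions in the order above, 10 gene lists by peaks per library and 2 genomic classes. With the block 3 of the 20 named regions no longer passed by limma, Zfp469 (adjusted p = 0.0519), Mrps27 (0.0590) and Oxsm (0.0637), nor did Mbp (0.0552). With total signal Rasgef1a did not (0.0706). In DIV3 against DIV1 all 11 regions called with the block were higher, so the lower regions, Ntn1 and Hes1 among them, no longer passed. Of 18 pairs of libraries with the same number, 2 had deviations correlated above 0.1 (from -0.0897 to 0.139), where pairing would need all of them, so the numbers were not taken to pair the samples. As a hint the other way, 8 of 12 libraries matched their own number best, and the mean correlation was 0.0258 for the same number and -0.0129 for others. Motif alternatives were not run. Depth limits the weak peaks: the median peak of DIV7 replicate 1 held 9 reads.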

Other observations

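Peaks on the X chromosome became a larger part of the lists with the day. Their share was 2.2 ± 0.527% at DIV1 (n = 3), 3.42 ± 1.19% at DIV3, 4.7 ± 1.05% at DIV5 and 4.95 ± 0.982% at DIV7 (r = 0.787, exact p = 0.00301; rho = 0.777, exact p = 0.00507; adjusted over 13 measures 0.0183). The share on chromosome 14, an autosome, also rose, from 4.92 ± 0.637 to 6.39 ± 0.452% (r = 0.701, exact p = 0.0126; rho = 0.605, exact p = 0.0451; adjusted 0.0183), so the rise was not particular to X. For X, within the 50-base libraries r was 0.401 (exact p = 0.467) and within the 51-base libraries 0.905 (exact p = 0.0333), and leaving out 2 DIV1 or DIV7 libraries gave r from 0.666 to 0.857. Of the shared regions that rose, 26 of 91 (28.6%) had a predicted gene (Gm or Rik name) nearest, against 6.7% of the others (Fisher's exact p = 2.11e-10, chosen after the values were seen), and of those that fell 10 of 160 (6.25%, exact p = 0.875).

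For the trend at shared regions, the tests of read length and depth were set before their results were seen, and the splits after. The real days gave 251 regions, and 1 of 100 splits of the libraries, the real one, reached this, the highest other giving 2, which argues against chance. Of 500 regions chosen in the 51-base libraries, 68.8% moved the same way in the 50-base libraries (exact one-sided p = 0.0111 over 90 orders), below the 75% set for excluding read length, so a part due to read length cannot be told apart, though 190 regions passed with read length as a term. With depth as a covariate this was 62.8% (exact one-sided p = 0.0889), and since reads in peaks fell with the day, depth may account for a part. Reads in peaks can themselves change with binding. This covariate therefore cannot separate the depth of sequencing from a change with the day. The design gives maturation and loss of dividing cells after day 2 as biological explanations, and these could not be separated from each other.

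For the fewer peaks at listed genes, the tests over all 8 falling lists were set before their results were seen, and those on 4 lists each after. A drift of peaks out of genes everywhere stays open for the 8 lists together, since 5 lay below the lowest 2.5% of random lists of genes of the same length. All 4 of the interneuron, oligodendrocyte, forebrain and Hox lists lay there, which argues against such a drift as the whole cause for them. Of the progenitor, granule neuron, axon and NFI and MEF2 lists 1 of 4 did (granule neuron genes, with 2.44% of random lists at or below), so for these it may be enough. For depth, 7 of the 8 lists, all but axon genes, lay beyond 2 SE of the change depth would give. That SE leaves out the spread of the observed change, so the count alone does not settle the question. Depth would give -0.340 of -4.87 peaks per 10000 for interneuron, -1.09 of -4.89 for oligodendrocyte and -0.666 of -4.10 for forebrain genes. These values argue against depth as the whole cause for these lists. It would give -4.29 of -8.64 for progenitor, -5.48 of -11.1 for granule neuron and -5.38 of -10.5 for NFI and MEF2 genes, so depth stays open there. Without the 3 libraries with fewest reads the progenitor, granule neuron, NFI and MEF2, axon (r = -0.518, adjusted exact p = 0.230) and Hox lists did not pass. DIV7 replicate 2 is then the only DIV7 library, so this cannot tell depth from the loss of the last day.

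For the X chromosome, the test of weak peaks was set before its result was seen, and the test of female cells after, with its bound on p added once the value was known. Among the 10000 strongest peaks of each library the X share also rose 3.72 times, from 0.697 to 2.59% (r = 0.722, exact p = 0.00723). These peaks were chosen by rank within a library, and the mean of the median maximum coverage fell from 6.33 at DIV1 to 4.67 at DIV7. The X chromosome held 1.35% of regions called in all 12 libraries and 3.76% of those called in 1. More weak peaks in later libraries therefore stay open as a cause. More cells of female origin could raise the X share but would lower the Y share; the latter had r = 0.531 with the day (exact p = 0.0771), and rho = 0.648 (exact p = 0.0292), with a mean of 0.455% at DIV1 and 1.78% at DIV7 (adjusted over 13 measures 0.1). These go against a fall of the Y share, but r did not pass its test, so this stays open.

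Splits of the libraries were also counted for the other results, chosen after they were seen except for DIV1 against the later days. For DIV7 against DIV1, DIV3 against DIV1 and DIV7 against DIV3, 1 of 10 splits, the real one, reached 232, 40 and 140 regions, with 0 as the highest other, and 10 splits are too few for a share under 0.05. For DIV5 against DIV3 and DIV7 against DIV5 all 10 of 10 splits gave 0. For the occupancy trend 1 of 100 splits, the real one, reached 6798 regions at an unadjusted p under 0.05, the highest other giving 3812, which argues against chance. Reads in peaks fell with the day, and the splits cannot tell depth from the day. For DIV1 against the later days 1 of 100 reached 8091, the highest other giving 7987, the split of DIV5 replicate 3, DIV7 replicate 1 and DIV7 replicate 3, which are the libraries with fewest reads in peaks.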
